A study of Arabidopsis thaliana with 12 samples.

How the data were processed

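RNA was measured in bulked seedlings of Arabidopsis thaliana of 2 genotypes, wild type (Col-0) and the mutant rbm25-1, either untreated or treated with abscisic acid (ABA). Per the labels' protocols, seeds were stratified for 4 days, seedlings grew on agar for 2 weeks, and ABA at 0.1 mM was sprayed 6 hours before harvest. The labels give the untreated groups as having had no treatment and name no mock spray. Polyadenylated RNA was the starting material per the labels, with 3 replicates in each of 4 groups, 12 samples in all. Whether the replicates were separate cultures is not stated.

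Per the submitters' processing notes, the software was Trimmomatic 0.32, TopHat2 2.0.13, Cufflinks 2.2.1 and Cuffdiff (no version given), with the genome build TAIR10. The notes give no settings for these tools. The authors deposited 6 tables, of which 3 hold genes and 3 hold splicing events, each comparing 2 of the groups. The comparisons are wild type with ABA against untreated wild type, untreated rbm25-1 against untreated wild type, and rbm25-1 with ABA against wild type with ABA. No table sets rbm25-1 with ABA against untreated rbm25-1.

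Per the file headers, the gene tables give the authors' value per group in FPKM (fragments per length of transcript, scaled to the mapped fragments of the sample), their log2 fold change, their p-value and their adjusted p-value, called q. The deposited log2 values carry no pseudocount. Where one group was listed at 0, the deposited log2 value was infinite or a spreadsheet error, and no fold is given here. Equal p-values had equal q in all 3 deposited gene tables, so that 1 adjustment spans the comparisons. The lowest FPKM in the higher of both groups was 0.547 in the deposited tables, so that genes with lower values had been left out upstream. A locus in these tables is a single gene, a merged group of genes printed here with its members joined by commas, or a transcribed stretch without a gene identifier.

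Per the file headers, the splicing tables give the authors' percent spliced in (PSI) per event and group, the signed difference in PSI as a score in percentage points, and an unadjusted p. The program and the test behind these p-values, and any read minimum, are not given in the sources used here. In each deposited table the commonest p among events with equal PSI in both groups was 0.42265. A few events (33, 28 and 28 in the order of comparisons above) were damaged in the deposited tables, with 4 PSI-like values in place of the expected columns, and were left out. For splicing, 1 event in each table had a deposited p of 0 with both PSI values at 0, and such an event is not read as a change.

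The tables hold 1 value per group and none per sample, and they hold no read totals. No test between replicates was therefore run here, no SD between replicates can stand beside a value, and the depth is unknown. The authors' p-values measure a spread between samples that may be technical. Confidence intervals given for shares are exact (Clopper-Pearson, 95%) and cover the counting of genes or events only. Genes and events are not independent replicates, which holds for each test across them.

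A gene was called changed at the authors' q under 0.05, with higher and lower values counted apart. For splicing events the deposited p-values were adjusted here by the Benjamini-Hochberg method within each table, with the same threshold. Merged loci and stretches without an identifier were counted among tested loci and left out of the tests of gene lists. Gene names, transcript lengths and GC content came from the reference annotation of the build TAIR10.1, and its coordinates were checked on the deposited introns, of which 95.9%, 96.2% and 95.5% had GT-AG ends in the 3 comparisons.

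The choice of comparisons, thresholds, tests, gene lists and named genes was made before the data were examined. The lists were ABA-inducible stress-protein genes, ABA synthesis and catabolism, PYR/PYL receptors, clade A PP2C phosphatases, SnRK2 kinases, ABA-related transcription factors, SR splicing factors, U1 snRNP and U2AF, nuclear photosynthesis genes, root markers, stomatal markers, seed storage and oil bodies, circadian clock, heat shock, salicylate and pathogen defence, jasmonate, auxin and expansins, wax and suberin, the plastid genome and the mitochondrial genome. The last pair served as a check of RNA quality and poly(A) selection, and the root, stomatal, seed and photosynthesis lists as tissue markers. Members whose identifier and name did not match in the annotation (U1C, PRP39A, GASA9 and HSP17.6C) were left out. Each list was tested with a two-sided Fisher's exact test of the members called up, and apart of those called down, against the other tested genes with 1 identifier. The p-values were adjusted by Benjamini-Hochberg over the 40 tests of a comparison (20 lists, 2 directions). A count adjusted over the list alone applies Benjamini-Hochberg to the authors' p-values of the list's members.

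The rule for named genes took RBM25 first. It then took the 10 largest positive and the 10 largest negative log2 fold changes among called genes with at least 5 FPKM in the higher group and a value above 0 in the lower group. From each list it took up to 4 called members with the largest absolute log2 fold change, of which 1 is not reported here. For splicing it took the 10 events with the smallest p among those past the threshold, and any passing event in the ABA and splicing-factor lists. Since 1 or 2 events passed in each table, other exons and introns are named below, and they were chosen after their values were seen.

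Overlaps between comparisons were tested with Fisher's exact test against the product of both counts divided by the number tested. Where a pair of comparisons shares a group, 100 simulations of unchanged groups gave the covariance that sharing alone produces. A standard error per gene was approximated as the absolute log2 fold change divided by the normal quantile of the authors' p. The simulations used the median of this standard error in each of 20 groups of genes of like expression. Such a median can understate the noisier genes, and with them the simulated covariance. Directions of splicing change were tested with a two-sided exact binomial test against equal numbers.

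The following steps were chosen after the values were seen. Log2 fold changes were centred on the median of genes of like transcript length and GC content, in 10 by 10 groups with at least 20 genes in each, and tested again with the approximate standard error. A gene passed after centring where its new p, not adjusted, was no higher than the largest p called as deposited. These limits were 0.02915, 0.0291 and 0.02915 in the order of comparisons above. Adjusted within each table they stand at 0.0519, 0.218 and 0.0913, so that counts after centring are laxer than an adjusted p under 0.05. The authors' p-values were adjusted again within each table. Differences between the mutant's effects with and without ABA were tested for each gene with the approximate standard errors. Directions of splicing change were counted at an unadjusted p under 0.05, and the p-values of both mutant comparisons were combined with their signs. Gene families of at least 8 tested members were tested as the lists were.

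The alternatives set beforehand were a q under 0.01, an absolute log2 fold change of at least 1, at least 1 FPKM, pseudocounts of 1 and 0.1, median centring, and a change of at least 10 percentage points in PSI. In data simulated with the measured length and GC trends, 7.11% of unchanged genes passed before centring and 0.431% after it in the comparison of genotypes under ABA. In the same simulation, 95% of genes changed by 1 on the log2 scale were recovered after centring, and 64% of those changed by 0.5. With no gene differing, the test of differences called 0 of 17563 simulated genes. With 194 of them differing by 1 it recovered 80.9% and called 11 others. These simulations drew normal noise from the approximate standard errors, and the trends put in were those that centring takes off. The simulated differences held no length or GC trend. Such simulations check the computation and do not give the error rate in the real data. Random lists gave an unadjusted p under 0.05 in 3.5%, 1% and 4% of tests in the 3 comparisons. The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.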

Results

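Gene expression and splicing were compared between seedlings of wild-type Arabidopsis (Col-0) and of rbm25-1, a mutant of the splicing factor gene RBM25 (AT1G60200), with and without abscisic acid (ABA), the hormone of drought and seed dormancy. The 12 samples form 4 groups of 3 replicates, and the values below are the authors' group values on TAIR10, with no SD. The comparisons ask how wild-type seedlings respond to ABA, and what rbm25-1 changes in gene expression and in splicing without and with the hormone.

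RBM25 itself was read first, as a check of the labels. The gene encodes a protein with an RNA recognition motif and a PWI domain and lies on chromosome 1 in a deposited locus from 22198347 to 22205347. In the authors' deposited table of untreated seedlings it fell from 9.15 FPKM in wild type to 2.55 in rbm25-1, a log2 fold change of -1.84 that left 27.9% of the wild-type level (q = 0.000132). With ABA, the authors' deposited table gives 9.26 FPKM in wild type and 1.46 in the mutant, a log2 fold change of -2.66 that left 15.8% (q = 0.000132). ABA itself gave RBM25 a log2 fold change of 0.02 in wild type, with q = 0.938 in the authors' deposited table. The neighbouring gene ULP1D (AT1G60220), which encodes a SUMO protease, fell with RBM25. It went from 7.87 to 2.23 FPKM untreated (log2 -1.82) and from 9.12 to 1.00 with ABA (log2 -3.18) in the authors' deposited tables. The next gene, AT1G60230, a radical SAM family member named after its values were seen, fell from 16.4 to 5.68 FPKM and from 7.32 to 2.27 in the same deposited tables of the authors. ULP1D and AT1G60230 share the deposited locus from 22208205 to 22214424 and their annotated ends overlap on opposite strands, so that reads there cannot be fully assigned to either gene.

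**Figure D1:**
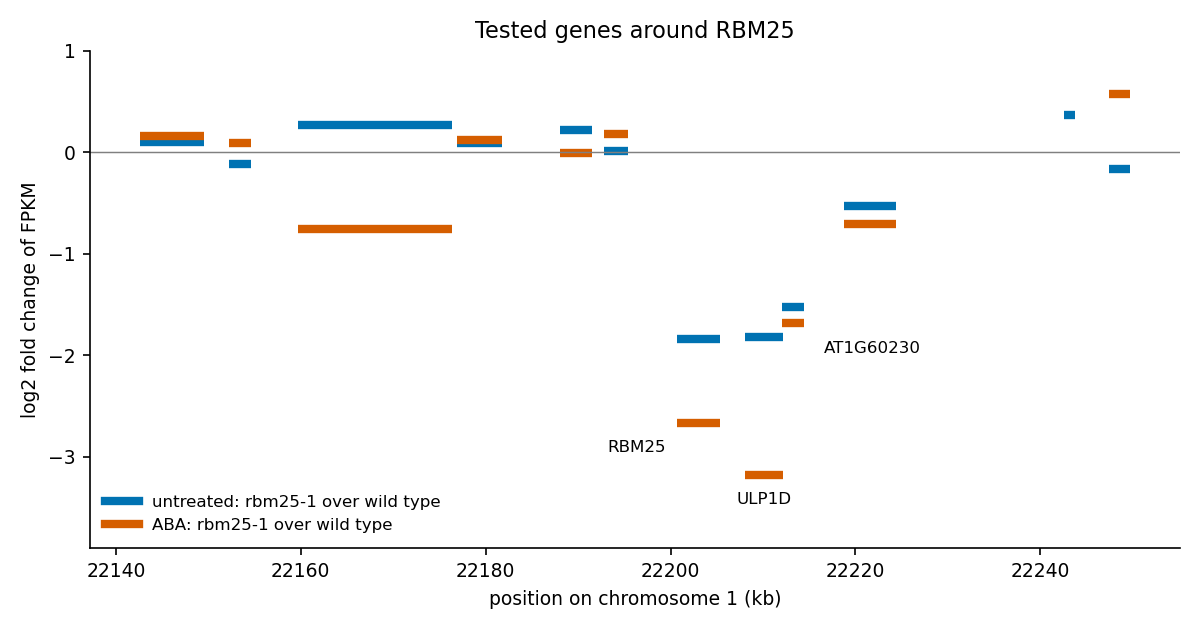
Log2 fold change of FPKM (rbm25-1 over wild type, vertical axis) of tested genes around RBM25, each drawn as a bar over its annotated span on chromosome 1 (horizontal axis, kb), in blue untreated and in orange with ABA. RBM25, ULP1D and AT1G60230 lie far below 0 in both conditions, with RBM25 at -1.84 untreated and -2.66 with ABA.

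In wild type, genes of stress protection led the rises with ABA. AT3G17520, a late embryogenesis abundant (LEA) protein gene, rose from 0.195 to 225 FPKM (log2 10.17), and the LEA gene AT3G02480 from 5.21 to 4959 FPKM (log2 9.89) in the authors' deposited table. RD29B (LTI65), a classic ABA-responsive gene, rose from 0.158 to 139 FPKM (log2 9.78), LEA7 from 1.31 to 861 FPKM (log2 9.36) and EM6 from 0.128 to 76.7 FPKM (log2 9.23) in the authors' deposited table. The others in this group of 10 were the LEA gene AT5G66780 at log2 9.61, AT3G03341 at 9.56, AT5G28520 at 9.16, BGLU24 at 9.13 and AT5G50360 at 9.12, each with the authors' deposited q at 0.00554 or below. The expansin gene EXPA8, of cell wall loosening, fell from 64.2 to 0.669 FPKM (log2 -6.58), and the ABA receptor gene PYL6 from 17.1 to 0.188 FPKM (log2 -6.51) in the authors' deposited table. RBCS1B, for the small subunit of Rubisco, fell from 617 to 12.1 FPKM (log2 -5.67) and PYL4 from 94.3 to 2.64 FPKM (log2 -5.16) in the authors' deposited table. Also among the 10 strongest falls of the authors' deposited table were AT5G63180 (log2 -5.82), RL6 (-5.44), RL4 (-5.32), AT2G47880 (-5.19), AT4G07820 (-5.19) and AT4G38860 (-5.18).

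Of 19647 tested loci, 11026 (56.1%) passed the authors' q under 0.05, with 5114 higher and 5912 lower after ABA. At least 2-fold changes were seen in 2310 of the former and 2287 of the latter. The untreated groups are labelled as having had no treatment, so that spraying goes together with ABA in this comparison, and whether all groups were harvested at the same time is not stated.

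The components that perceive and relay ABA moved in different directions. Of 10 tested PYR/PYL receptors, 8 fell and 0 rose (adjusted p = 0.00615, Fisher's exact test), among them PYL5 at log2 -2.72 and PYR1 at -1.91 in the authors' deposited table. Of 9 clade A PP2C phosphatases, which restrain ABA signalling, 8 rose (adjusted exact p = 0.000853). HAI2 rose from 0.183 to 40.0 FPKM and PP2CA from 50.8 to 469, while HAI1 had log2 6.68 and ABI2 4.23 in the authors' deposited table. Of 10 SnRK2 kinases 6 rose and 3 fell (adjusted exact p = 0.0515 for rises), with SNRK2.7 at log2 1.96, SNRK2.6 at 1.91, SNRK2.9 at 1.26 and SNRK2.8 at -1.09 in the authors' deposited table. Of 11 genes of ABA synthesis and catabolism, 10 rose (adjusted exact p = 8.23e-05). The most raised were the catabolic genes CYP707A1, from 2.15 to 66.8 FPKM, CYP707A4 (log2 4.46), CYP707A3 (3.88) and CYP707A2 (3.70) in the authors' deposited table. Of 21 ABA-related transcription factors, 19 rose and 1 fell (adjusted exact p = 1.30e-08), led by MYB102 (log2 7.17), NAC019 (5.95), HB-7 (4.32) and MYB41 (4.16) in the authors' deposited table. Of 21 ABA-inducible stress-protein genes, 19 rose and 0 fell (adjusted exact p = 1.30e-08), among them LEA4-5 from 1.62 to 473 FPKM in the authors' deposited table.

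Genes of growth and photosynthesis fell with ABA, and genes of the plant surface rose. Of 21 nuclear photosynthesis genes 20 fell and 0 rose (adjusted exact p = 1.30e-08), with RBCS2B at log2 -3.45, RBCS3B at -2.11 and PSAD1 at -1.93 in the authors' deposited table. Of 16 auxin and expansin genes 11 fell and 3 rose (adjusted exact p = 0.00615), with SAUR15 at log2 -4.52, EXPA1 at -3.61 and GH3.3, an enzyme of auxin conjugation, at 5.07 in the authors' deposited table. Of 16 root markers 14 fell and 1 rose (adjusted exact p = 2.65e-05), with HKT1 at log2 -2.82, CASP4 at -2.67 and PLT1 at -1.76 in the authors' deposited table. Of 9 stomatal markers 7 fell and 1 rose (adjusted exact p = 0.0139). MYB60 had log2 -2.19, EPF1 -1.65, MUTE -1.16 and the potassium channel gene KAT1 1.15 in the authors' deposited table. All 13 wax and suberin genes rose (adjusted exact p = 2.61e-07), with WSD1 at log2 4.11, CER1 going from 4.61 to 79.2 FPKM, KCS2 at log2 3.77 and FAR1 at 3.55 in the authors' deposited table.

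Of 18 SR splicing factors 13 fell and 1 rose (adjusted exact p = 0.00147), with SR34 at log2 -1.09, SCL30A at -0.85, SCL30 at -0.73 and SR30 at 0.66 in the authors' deposited table. That list call was lost after centring on length and GC, with 5 falling and 3 rising (adjusted exact p = 1), and among changes of at least 2-fold (adjusted exact p = 0.865). Of 11 genes of U1 snRNP and U2AF 4 fell (adjusted exact p = 0.827), with U2AF35A at log2 -0.65, U2AF35B at -0.59, U2AF65A at -0.41 and U1-70K at -0.34 in the authors' deposited table, and after centring 1 fell and 3 rose. Of 7 jasmonate genes 5 rose and 1 fell (adjusted exact p = 0.0391), a call lost after centring (adjusted exact p = 0.0534, with 5 still rising and the list's median log2 at 0.80 against 0.74 before) and at 2-fold (adjusted exact p = 0.787). Its named members were JAZ1, a repressor of jasmonate signalling, at log2 2.74, JAZ5 at 1.00, LOX2 at 0.86 and the defensin gene PDF1.2A at -0.94 in the authors' deposited table. Of 8 salicylate and defence genes 5 rose and 1 fell (adjusted exact p = 0.0656, and 0.0223 with 6 rising after centring), with PAD3 at log2 4.05, WRKY33 at 3.10, PR2 at 1.13 and WRKY70 at 1.01 in the authors' deposited table.

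Of 8 heat shock genes 4 rose (adjusted exact p = 0.291, and 0.0324 at 2-fold). HSP22.0 was listed at 0 untreated and 32.3 FPKM with ABA, HSP17.4 had log2 6.80, HSP70 2.03 and HSP90.1 1.17 in the authors' deposited table. Of 7 clock genes 1 rose and 2 fell, with GI at log2 -1.32, ELF4 at 0.88 and PRR7 at -0.77, and of 2 seed genes OLEO2 rose (log2 0.96) in the authors' deposited table. No plastid gene of 12 was called, with 0 at an unadjusted p under 0.05 in the authors' deposited Cuffdiff values, and of 12 mitochondrial genes ATMG00030 rose (log2 0.59). Of these 12, which serve as a check of RNA quality and poly(A) selection, 11 had a log2 above 0, with a median of 0.98. Among them 4 had an unadjusted p under 0.05 in the authors' deposited table. The plastid list does not cover the merged plastid group ATCG00120 to ATCG00220. The values of that group, given below with the mutant comparisons, were far higher in wild type with ABA than in untreated wild type. Counts adjusted over the list alone were the same, except for 12 falls among auxin and expansin genes. After centring on length and GC, U2AF35A, U2AF65A and U1-70K no longer passed.

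Few splicing events of wild-type seedlings passed the adjusted p. Of 10502 events, 1 did, and it had no change in PSI, while 507 (4.83%) had an unadjusted p under 0.05 in the authors' deposited table. SR30, chosen after its values were seen, encodes an SR protein whose own transcript is alternatively spliced. An alternative acceptor of SR30 had 49.3% PSI untreated and 16.8% with ABA (unadjusted p = 0.000869) in the authors' deposited table. Among cassette exons with an unadjusted p under 0.05, 25 had lower and 12 higher inclusion with ABA (67.6% lower, exact binomial p = 0.0470, adjusted p = 0.196). Among retained introns 43 had higher and 36 lower retention (54.4%, exact binomial p = 0.50).

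Without ABA, rbm25-1 seedlings differed from wild type at fewer genes, with defence and light-harvesting genes among the higher ones. PR1, the pathogenesis-related gene of the salicylate response, is merged with PRB1 in the tables and rose from 41.3 to 242 FPKM (log2 2.55), and AT4G33720, of the same CAP protein family, from 5.24 to 39.8 (log2 2.92) in the authors' deposited table. PCR1, a gene of cadmium resistance, rose from 7.58 to 43.5 FPKM (log2 2.52), and CAB2 (LHCB1.1), of the light-harvesting antenna, from 155 to 830 FPKM (log2 2.42) in the authors' deposited table. HEI10, a gene of meiotic crossover formation, fell from 24.6 to 3.29 FPKM (log2 -2.90), and QQS, a gene that affects starch content, from 31.2 to 5.78 (log2 -2.43) in the authors' deposited table. CAF1a, for an mRNA deadenylase, fell from 57.9 to 7.48 FPKM (log2 -2.95), DIC2, for a mitochondrial dicarboxylate carrier, fell by 3.21 on the log2 scale, and STZ, for a zinc finger protein of stress responses, fell from 20.3 to 5.34 (log2 -1.93) in the authors' deposited table.

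Genes of unknown function held the extremes. AT3G51642 rose from 2.55 to 97.7 FPKM (log2 5.26), and AT2G01422 fell from 31.2 to 1.26 (log2 -4.63) in the authors' deposited table. A merged group of plastid genes, ATCG00120 to ATCG00220, rose from 11.9 to 389 FPKM (log2 5.03) in the authors' deposited table. Also named were AT2G17490.1 (log2 3.34), AT1G34047 (3.23), a stretch without identifier on chromosome 1 from 12942527 to 12942891 (3.02), AT4G04293.1 (2.55), AT4G08093 (-2.36) and AT4G27657 (-2.02) of the authors' deposited table. Of 19327 tested loci, 2579 (13.3%) passed, 1188 higher and 1391 lower in the mutant, with 142 and 130 of them at least 2-fold. The count of 2579 rests on the authors' adjustment over several comparisons, and adjusted within this table alone 1126 passed (516 higher, 610 lower).

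Salicylate and defence genes of the fixed list rose without ABA, 5 of 8 with 0 falling (adjusted exact p = 0.00152). PR2 went from 3.46 to 11.3 FPKM (log2 1.71), PAD3, of camalexin synthesis, had log2 0.94, PAD4 0.41 and EDS1 0.38 in the authors' deposited table. Adjusted within the table, 2 of the 8 passed and the list call was lost (adjusted exact p = 0.163), as it was at 2-fold (adjusted exact p = 0.499). Of 7 jasmonate genes 4 fell and 0 rose (adjusted exact p = 0.010), a call lost at 2-fold (adjusted exact p = 1). These were OPR3 (log2 -0.71), LOX2 (-0.71) and AOS (-0.56), enzymes of jasmonate synthesis, and the repressor JAZ1 (-0.68) in the authors' deposited table. Of 21 nuclear photosynthesis genes 7 rose and 1 fell (adjusted exact p = 0.00314), with LHCB2.1 at log2 1.22, LHCB2.2 at 1.01 and LHCB1.2 at 1.00 in the authors' deposited table. LHCB and RBCS copies are nearly identical, so that reads of one copy can be counted for another.

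The ABA lists did not stand apart from other genes in untreated seedlings. Of 18 ABA-inducible genes 3 rose and 1 fell (adjusted exact p = 0.494), with KIN1 at log2 1.00, ADH1 at 0.75, RD22 at 0.42 and RAB18 at -0.46 in the authors' deposited table. Of 9 genes of ABA synthesis and catabolism 2 rose, ABA1 (log2 0.66) and AAO3 (0.43), and 2 fell, NCED3 (-0.65) and BGLU18 (-0.33), in the authors' deposited table. Of 9 receptors PYL2 (log2 0.73) and PYR1 (0.39) rose, of 6 PP2C genes HAI1 (-0.39) and PP2CA (-0.36) fell, and of 10 SnRK2 genes SNRK2.9 (-0.31) fell in the authors' deposited table. Of 19 ABA-related transcription factors WRKY60 (log2 0.62) rose while RD26 (-0.53), NAC055 (-0.47) and MYB44 (-0.35) fell in the authors' deposited table. Of 18 SR factors SR34B (log2 -0.41) and RS2Z33 (-0.37) fell, and of 11 genes of U1 snRNP and U2AF the U1-associated LUC7B (0.60) and LUC7RL (0.52) rose in the authors' deposited table.

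In the other lists of untreated seedlings the smallest adjusted exact p was 0.32. Of 17 root markers IRT1 (log2 3.03) and CASP5 (1.04) rose and CASP4 (-0.65) fell, of 2 seed genes CRA1 (-2.11) fell, of 8 clock genes PRR7 (0.69) rose and of 5 heat shock genes HSP90.1 (0.69) rose in the authors' deposited table. Of 16 auxin and expansin genes EXPA1 (log2 0.44) rose and IAA14 (-0.43) fell, and of 12 wax and suberin genes CYP86B1 (0.53) and CYP86A1 (0.32) rose and FAR4 (-0.38) fell in the authors' deposited table. No stomatal marker of 9 was called by the authors' Cuffdiff values, with 1 at an unadjusted p under 0.05. Of 12 plastid genes ATCG00430 (log2 1.31), ATCG01010 (0.35) and ATCG00490 (0.33) rose, and of 9 mitochondrial genes ATMG00030 (0.65) rose in the authors' deposited table. The median log2 was 0.34 over the plastid list and -0.14 over the mitochondrial list. Counts adjusted over the list alone were the same but for 1 rise among receptors, 1 fall among PP2C genes, 0 calls among SnRK2 and SR genes, 2 rises and 0 falls among root markers, 1 rise and 0 falls among wax genes and 1 rise among plastid genes.

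Of 66 genes with an identifier named in this comparison, 50 passed with the adjustment within the table, and the stretch on chromosome 1 did not. The others that did not were BGLU18, PYL2, HAI1, PP2CA, SNRK2.9, MYB44, SR34B, RS2Z33, CASP4, PAD4, EDS1, IAA14, FAR4, CYP86A1, ATCG01010 and ATCG00490. After centring on length and GC, AAO3, HAI1, SNRK2.9, MYB44, RS2Z33 and FAR4 no longer passed.

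With ABA, defence genes were again higher in rbm25-1 than in wild type, and HEI10 and COR15A were among the lower genes. PR1 merged with PRB1 rose from 26.9 to 255 FPKM (log2 3.24) and PR2, a glucanase gene, from 7.58 to 43.2 (log2 2.51) in the authors' deposited table. LURP1, a gene of defence against downy mildew, rose from 6.45 to 47.1 FPKM (log2 2.87), GSTU12, for a glutathione transferase, from 2.21 to 19.4 (log2 3.13) and PCR1 from 0.892 to 9.94 (log2 3.48) in the authors' deposited table. HEI10 fell from 21.5 to 2.18 FPKM (log2 -3.30), as it did without ABA, and COR15A, for a chloroplast cryoprotectant, fell from 1570 to 705 (log2 -1.15) in the authors' deposited table. The receptor gene PYL8 fell from 113 to 64.6 FPKM (log2 -0.81), and the fatty acyl reductase gene FAR4, of suberin, from 24.4 to 8.37 (log2 -1.55) in the authors' deposited table.

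A stretch without identifier on chromosome 1, from 28515287 to 28515910, went from 0.275 to 38.9 FPKM (log2 7.14), and the merged plastid group ATCG00120 to ATCG00220 fell from 246 to 11.97 (log2 -4.36) in the authors' deposited table. Also named as higher were AT5G24240,AT5G24250 (log2 3.60), AT2G01022.1 (3.29), BGLU27 (2.93) and AT5G46960 (2.54), and as lower AT5G10336 (11.8 to 0.742 FPKM), AT1G52857 (log2 -2.97), AT3G52535 (-2.91), AT1G07901 (-2.60), AT2G29995 (-2.40) and AT2G01422 (-2.27) of the authors' deposited table. Of 19244 tested loci, 6147 (31.9%) passed, 3402 higher and 2745 lower in the mutant, with 251 and 344 at least 2-fold, and 4947 passed when adjusted within the table.

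The fold changes of this comparison moved with transcript length and GC content, which bears on each gene group below. Across 16115 genes, Spearman's rho was 0.368 with length and 0.451 with GC, against 0.163 and -0.0479 without ABA and 0.0426 and -0.173 for ABA in wild type. With protein-coding genes split into 5 groups of equal size by GC, 1209 were higher and 146 lower in the group of highest GC, and 166 higher and 1070 lower in that of lowest GC. After centring on length and GC 4431 loci passed the unadjusted limit, 2130 higher and 2301 lower, and 54.4% of the original calls were kept.

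**Figure D2:**
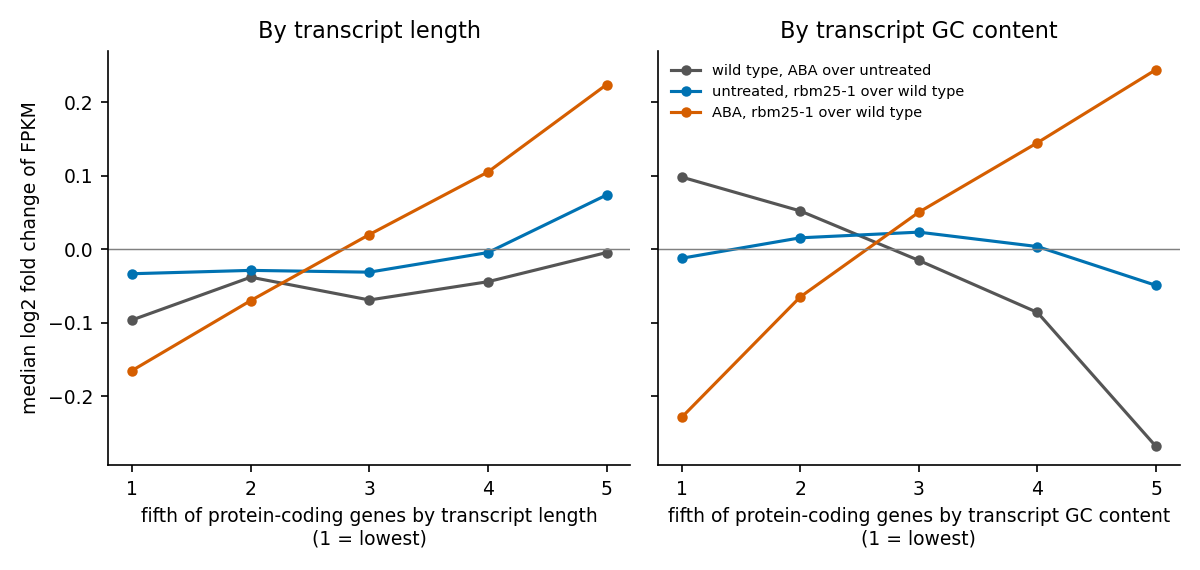
Median log2 fold change (vertical axis) of protein-coding genes in 5 groups of equal size by transcript length and, in the other panel, by GC content (horizontal axes, group 1 lowest), with 1 line per comparison. The line for rbm25-1 against wild type with ABA climbs from -0.16 to 0.22 across length and from -0.23 to 0.24 across GC.

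Of 8 salicylate and defence genes 7 rose and 0 fell with ABA (adjusted exact p = 0.00132, and 5.49e-05 after centring). PAD3 went from 30.3 to 114 FPKM (log2 1.91), ICS1, of salicylate synthesis, from 5.69 to 14.4 (log2 1.34) and PAD4 had log2 0.57 in the authors' deposited table. Of 21 nuclear photosynthesis genes 12 rose and 0 fell (adjusted exact p = 0.00132, and 0.000557 after centring), with LHCB2.1 going from 24.1 to 57.1 FPKM, LHCB2.2 at log2 1.19, LHCB1.1 at 1.04 and RBCS3B at 0.83 in the authors' deposited table. Of 7 jasmonate genes 3 rose and 1 fell (adjusted exact p = 0.374, and 0.00366 with 5 rising after centring). PDF1.2A rose from 10.2 to 25.7 FPKM and LOX2 from 32.8 to 75.9, AOS had log2 0.74 and OPR3 -0.32 in the authors' deposited table. Of 9 stomatal markers 4 rose (adjusted exact p = 0.355, and 0.0136 with 5 rising after centring), namely MUTE (log2 0.99), SPCH (0.67), KAT1 (0.58) and TMM (0.44) in the authors' deposited table.

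**Figure D3:**
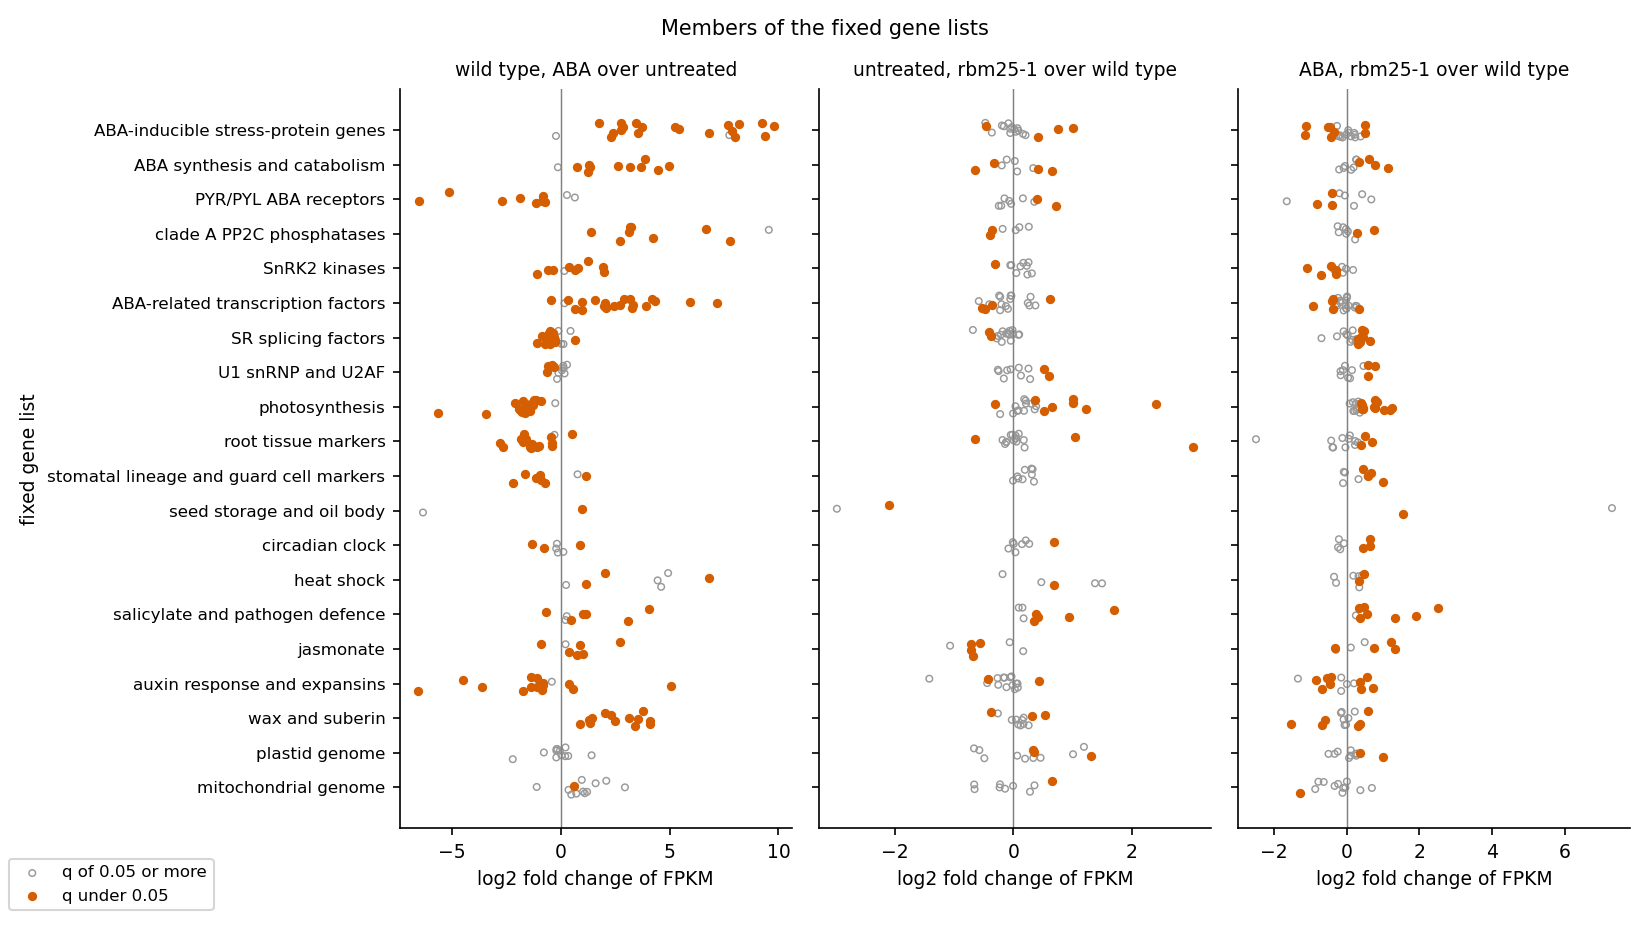
Log2 fold change of FPKM (horizontal axis) of the members of the fixed gene lists (vertical axis, 1 line of points per list) in the 3 comparisons, filled where q was under 0.05 and open elsewhere. Members with a group at 0 are not drawn, the vertical scatter within a list has no meaning, and 19 of 21 ABA-inducible genes were higher with ABA in wild type.

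Of 21 ABA-inducible genes 2 rose and 6 fell in the mutant under ABA (adjusted exact p = 0.374 for falls), with COR15B at log2 -1.13, KIN2 at -0.51 and EM1 at 0.50 in the authors' deposited table. Of 10 SnRK2 kinases 5 fell (adjusted exact p = 0.0858), among them SNRK2.9 (log2 -1.10), SNRK2.7 (-0.70), SNRK2.3 (-0.45) and SNRK2.2 (-0.31) in the authors' deposited table. Of 9 receptors PYL8, PYL5 (log2 -0.41) and PYL9 (-0.40) fell, and of 9 PP2C genes AHG1 (0.75) and ABI2 (0.29) rose in the authors' deposited table. Of 11 genes of ABA synthesis and catabolism 4 rose, NCED2 (log2 1.13), BGLU18 (0.76), ABA1 (0.61) and CYP707A2 (0.33), in the authors' deposited table. Of 21 ABA-related transcription factors 1 rose and 4 fell, MYB41 (log2 -0.94), ABF1 (-0.42), MYB102 (-0.39) and HB5 (-0.37), in the authors' deposited table. Of 18 SR factors 8 rose (adjusted exact p = 0.0858), among them SR30 (log2 0.63), SR45A (0.48), SR34 (0.44) and SR45 (0.41), and of 11 genes of U1 snRNP and U2AF the 3 LUC7 genes rose, LUC7B (0.78), LUC7RL (0.59) and LUC7A (0.59), in the authors' deposited table.

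The remaining lists did not pass under ABA. Of 14 auxin and expansin genes 4 rose and 5 fell (adjusted exact p = 0.292), with GH3.3 at log2 0.71, EXPA5 at 0.56, IAA17 at -0.70 and IAA3 at -0.85 in the authors' deposited table. Of 13 wax and suberin genes 3 rose and 3 fell, with CYP86A1 at log2 0.57, WSD1 at -0.61 and FAR5 at -0.68, and of 14 root markers PRP3 (0.70), EXPA7 (0.50) and SHR (0.38) rose in the authors' deposited table. Of 4 seed genes 2 rose, OLEO2 (log2 1.55) and CRU3, listed at 0 in wild type and 0.590 FPKM in the mutant, of 7 clock genes GI (0.63), PRR5 (0.62) and PRR7 (0.46) rose, and of 8 heat shock genes HSP22.0 (0.47) and HSP90.1 (0.35) rose in the authors' deposited table. Of 11 plastid genes ATCG00430 (log2 0.99) and ATCG00490 (0.35) rose, and of 12 mitochondrial genes ATMG00690 (-1.29) fell in the authors' deposited table, with medians of 0.11 and -0.18 over the lists. Counts adjusted over the list alone were the same but for 2 falls among receptors, 1 rise among PP2C genes, 0 rises among ABA-related transcription factors, 2 rises among root markers, 1 rise among heat shock genes, 0 calls among plastid genes and 0 among mitochondrial genes.

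Centring on length and GC turned several of these list counts. After it, 1 SR factor rose and 3 fell, 2 clock genes rose and 3 fell, 1 PP2C gene rose and 2 fell, 3 ABA-related transcription factors rose and 6 fell, and of the ABA-inducible genes 0 rose and 3 fell. Rises and falls were then 1 and 2 among receptors, 0 and 3 among SnRK2 genes, 3 and 0 in ABA synthesis and catabolism, 3 and 2 in U1 snRNP and U2AF, 2 and 2 among root markers, 3 and 3 among auxin and expansin genes and 2 and 5 among wax and suberin genes. The smallest adjusted exact p among these lists after centring was 0.097.

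Of 83 genes with an identifier named under ABA, 75 passed with the adjustment within the table, and PYL9, ABI2, SNRK2.2, SHR, MUTE, SPCH, HSP90.1 and OPR3 did not. After centring on length and GC, KIN2, EM1, CYP707A2, PYL9, AHG1, SNRK2.2, MYB102, SR45A, SR34, SR45, SHR, TMM, GI and HSP90.1 no longer passed.

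The mutant's effects with and without ABA overlapped. Among 17568 genes tested in both, 534 were higher in both (189.9 expected by chance, exact p = 3.99e-138) and 565 lower in both (175.2 expected, exact p = 2.43e-173). Of 1231 genes called in both, 1099 (89.3%) had the same direction, and Spearman's rho across genes was 0.311. At least 2-fold changes in the same direction were seen in 91 of 17525 genes, RBM25, ULP1D, HEI10, PCR1 and PR2 among them.

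Genes that ABA changed in wild type were compared with the mutant's effect, in pairs of comparisons that share a group. Higher with ABA in wild type and lower in the mutant under ABA were 991 genes (684.4 expected), and the reverse held for 1286 (943.6 expected). The covariance of both fold changes was -0.0422, against -0.0122 in simulations in which sharing wild type with ABA alone acts, and it was -0.022 after centring on length and GC. Higher with ABA and higher in the untreated mutant were 428 genes (269.2 expected), and lower in both were 642 (401.8 expected), with a covariance of 0.0398 (0.0363 after centring) against 0.0122 simulated. The response of rbm25-1 to ABA can be described from the group values alone, without a test. Over 15842 genes its SD across genes was 0.995 times that of wild type, and Pearson's r between both responses was 0.927. Of 1700 genes raised at least 2-fold in wild type, 1697 were also higher with ABA in the mutant, with a median log2 of 1.63 against 1.68, and 83.5% reached 2-fold there. Of 1501 genes lowered at least 2-fold, 1494 were also lower, with medians of -1.35 in the mutant and -1.42 in wild type, and 71.95% reached 2-fold in the mutant. The response was smaller in the mutant for 59.8% of the raised and 63.1% of the lowered genes, which were chosen on the wild-type response itself.

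Splicing in rbm25-1 was marked by lower inclusion of cassette exons, the exons that a transcript can include or skip. At an unadjusted p under 0.05, 119 of 123 such exons in untreated seedlings were included less in the mutant (96.7%, exact interval 91.9% to 99.1%, exact binomial p = 1.77e-30). With ABA it was 129 of 132 (97.7%, 93.5% to 99.5%, exact binomial p = 1.41e-34). Over all cassette exons with a change, whatever their p, 82.7% untreated and 83.9% with ABA were included less. Of the 410 cassette exons found in both tables, 71 had such a p in both (32.5 expected, exact p = 1.00e-19), and these 71 all had lower inclusion in both. The differences with and without ABA had a Spearman's rho of 0.577 across exons (permutation p = 1e-04, the smallest that the permutations can give).

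**Figure D4:**
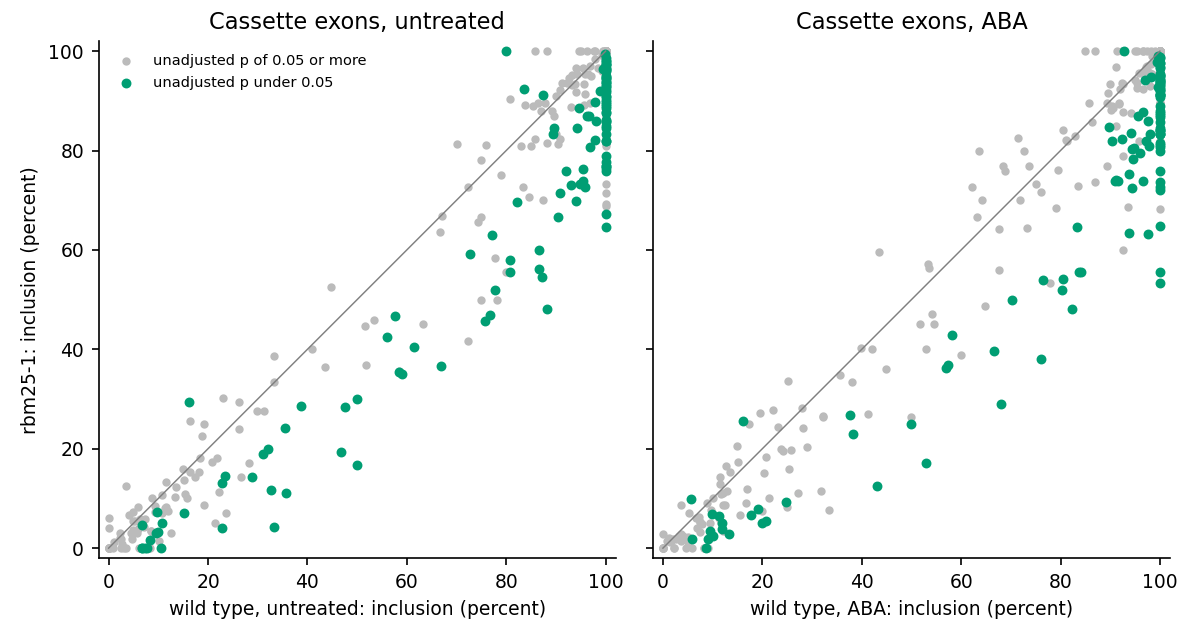
Inclusion (percent) of 410 cassette exons in wild type (horizontal axis) and rbm25-1 (vertical axis), untreated and with ABA, each point an exon, in green where the unadjusted p was under 0.05 and in grey elsewhere. Most green points lie under the diagonal of equal inclusion.

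Several of these exons are named here, chosen after their values were seen, and none of them passed the adjusted p of a single comparison. A 48-nt exon of AT2G45380 (chromosome 2, 18701098 to 18701145) went from 88.2% to 48.1% PSI untreated and from 82.3% to 48.1% with ABA in the authors' deposited tables. In CIPK3, a kinase gene of calcium and ABA signalling, a 54-nt exon (chromosome 2, 11516427 to 11516480) had 32.7% and 11.7% untreated and 24.9% and 9.32% with ABA in wild type and mutant of the authors' deposited tables. A 104-nt exon of P5CS1, the gene of the rate-limiting enzyme of proline synthesis, had 100% and 86.2% untreated and 97.2% and 81.9% with ABA in the authors' deposited tables. A 96-nt exon of the SR-like gene SR45A (chromosome 1, 2258750 to 2258845) had 46.7% and 19.4%, then 52.9% and 17.1% with ABA, and a 50-nt exon of LUC7B 35.7% and 11.1%, then 43.1% and 12.5%, in the authors' deposited tables. In FC2, for a ferrochelatase, inclusion was 76.7% and 46.9% untreated and 68.0% and 29.1% with ABA in the authors' deposited tables. The SR30 acceptor noted above had 49.3% and 33.3% untreated and 16.8% and 6.41% with ABA in the authors' deposited tables. With the signed p-values of both comparisons combined, 171 of 7547 shared events passed an adjusted p of 0.05, 121 lower and 50 higher in the mutant, and of 58 cassette exons among them 57 were lower.

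Retained introns gave a less uniform picture. With ABA 116 introns at an unadjusted p under 0.05 were more retained in the mutant and 44 less (72.5% more, exact interval 64.9% to 79.3%, exact binomial p = 1.13e-08). That share was 53.0% over all introns with a change, and 53.8% over those of mean inclusion between 20% and 80% (exact binomial p = 0.0756). In untreated seedlings 65 were more and 44 less retained (59.6%, exact binomial p = 0.0549), and over all introns with a change the share was 48.2%. An intron of IMPA-2, an importin alpha gene, had 10.5% retention in wild type and 36.8% in the mutant untreated, and 14.4% and 50% with ABA in the authors' deposited tables. An intron of HAB1, a clade A PP2C gene (chromosome 1, 27392394 to 27392516), had 15.1% in wild type and 44.2% in the mutant with ABA (unadjusted p = 0.0035, adjusted p = 0.441) in the authors' deposited table. Other HAB1 retention events had lower values in the mutant, 86.7% and 78.3% in one case (unadjusted p = 0.341), and an intron of ABI2, of the same phosphatase clade, had 92.3% and 82.4% (unadjusted p = 0.0115) in the authors' deposited table. These introns were chosen after their values were seen.

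Single events seldom passed the adjusted p. Untreated, 1 of 9849 events passed, with no change in PSI, and 604 (6.13%) had an unadjusted p under 0.05 in the authors' deposited table. With ABA 2 of 11170 passed, and 715 (6.40%) had an unadjusted p under 0.05. Of these 2, AT4G34265 had an alternative donor (adjusted p = 0.0223) and the other no change in PSI in the authors' deposited table. The 45-nt stretch of AT4G34265 (chromosome 4, 16402736 to 16402780) had 2.99% and 17.1% PSI in wild type and mutant of the authors' deposited table. The same direction was found in 197 of 198 events with an unadjusted p under 0.05 in both mutant comparisons (46.4 expected, exact p = 4.12e-82). Genes with changed splicing and changed expression were 0 in each comparison by the adjusted p. At an unadjusted p under 0.05 for splicing they were 246 for ABA in wild type (204 expected, exact p = 3.74e-06), 75 for the untreated mutant (56.6 expected, exact p = 0.00846) and 216 for the mutant under ABA (179 expected, exact p = 0.000349). Genes were not matched on expression level or number of events, either of which can favour both calls. The excess therefore does not show a link between splicing and expression.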

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

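Tests in this part chosen only after the result was seen were the test of differences between the mutant's effects, with its repeat after centring on length and GC, and the permuted orders of loci. The count of groups of like GC that kept a trend with length was also chosen then.

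For 48 of the 112 genes named in either mutant comparison and measured in both, the effect of rbm25-1 with ABA differed from its effect without ABA. These genes were named for a called or large effect in either of the comparisons tested here. That choice favours a difference, so that their share cannot be set against that of all genes. Each difference passed an approximate test adjusted over 17569 genes, in which 1200 passed, and 566 did after centring on length and GC. Values below are the mutant's log2 fold change with ABA minus that without, from the authors' deposited tables.

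The effect was lower with ABA, also after centring, for the ABA-inducible genes KIN1 (-1.44) and COR15B (-1.11), the receptor gene PYL8 (-0.97), the suberin gene FAR4 (-1.17), the root marker CASP5 (-0.96) and the light-harvesting gene CAB2 (LHCB1.1; -1.38). RBM25 (-0.82) and its neighbour ULP1D (-1.36) differed in the same direction, as did AT4G33720 (-0.92), AT2G29995 (-1.57), AT3G52535 (-1.44), AT5G10336 (-3.71) and AT3G51642 (-6.61).

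The effect was higher with ABA, also after centring, for LOX2 (1.92), AOS (1.31), JAZ1 (0.79) and PDF1.2A (1.17) of the jasmonate list and ICS1 (1.18) and PAD3 (0.97) of the salicylate and defence list. It was also higher for BGLU18 (1.09), of the list of ABA synthesis and catabolism, and for LURP1 (0.93). Other genes of this direction were STZ (2.21), CAF1a (2.32), DIC2 (2.78), GSTU12 (2.74), PCR1 (0.96), SR30 (0.64), RBCS3B (0.61), AT2G01422 (2.36) and AT4G27657 (1.57).

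Centring could not be applied to loci without a length and GC value, and their differences stand as deposited. These were the merged plastid group ATCG00120 to ATCG00220 (-9.39), higher in the untreated mutant and lower in the mutant with ABA, ATMG00030 (-0.77), merged PRB1,PR1 (0.69), AT2G01022.1 (1.38) and merged AT5G24240,AT5G24250 (2.1).

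For 13 genes the difference passed as deposited and no longer passed after centring. These were AT1G52857 (-3.52), COR15A (-1.0), FAR5 (-0.94), SNRK2.7 (-0.94), SNRK2.9 (-0.79), KIN2 (-0.68), IAA17 (-0.67), IAA3 (-0.60), SR45 (0.59), PRP3 (0.66), PR2 (0.80), NCED3 (0.84) and GH3.3 (0.86). They kept their sign, with centred values from -3.23 for AT1G52857 to 0.61 for PR2, so that the lost call does not show that a difference is absent. Some differences shrank, however. GH3.3 and NCED3, at 0.86 and 0.84 as deposited, had centred values no higher than the 0.61 of PR2.

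ULP1D fell with its neighbour RBM25 in both mutant comparisons. Reads shared by both genes are argued against by a gap of 2857 bp between the deposited loci. Chance is argued against, since with genes of 1 deposited locus joined, a neighbour of RBM25 was lowered at least 2-fold in both comparisons in 72 of 10000 permuted orders, although 2195 held a pair changed in the same direction somewhere in the genome. A wider stretch of altered sequence may be linked to the mutation and cannot be told apart from an effect of RBM25 itself in this single mutant line. Of 10 other tested loci within 50 kb, only AT1G60230, which shares the deposited locus of ULP1D, changed at least 2-fold in both. Elsewhere 0.541% did (Fisher's exact p = 0.0533), and without AT1G60230 the count is 0 of 9. Below 2-fold, the next tested locus beyond AT1G60230, merged BGLU5 and BGLU6, was also called lower in both, at log2 -0.53 untreated and -0.71 with ABA. The remaining tested loci of the window were not called in both.

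Cassette exons were included less in rbm25-1. A ceiling near full inclusion is argued against, because among exons of mean inclusion between 20% and 80% the lower 95% bound of the share that fell was 64.6% in the comparison where it was lower. Deeper mutant libraries showing more skipping are argued against as well, because among exons under 100% in both groups that bound was 71.9%. The differences with and without ABA correlated across exons at a Spearman's rho of 0.577, as predicted for an effect of the genotype. Traits of an exon that act alike in both comparisons, such as its room to fall, could also give a correlation. It therefore does not single out the genotype by itself. Whether RBM25 itself or the lower ULP1D and AT1G60230 of the same line act on these exons was not tested.

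The mutant's fold changes under ABA rose with transcript length. A technical difference between the sets of libraries may be the source, since the trend was also present in intronless genes (Spearman's rho 0.323). Loss of a splicing factor acting through introns predicted a correlation with the number of introns above 0.1 among transcripts of 1000 to 2000 nt. It was -0.0379 there, and 0.12 over transcripts of any length. GC content, with a correlation of 0.451 over all genes, was not held alike, so that the test cannot exclude an effect through introns. The trend in intronless genes shows only that introns are not needed for it. Within 10 groups of like GC the median correlation with length was 0.334. To argue against GC content as the whole cause, the rule set beforehand asked for a correlation above 0.1 in each group. The group of lowest GC, with a correlation of 0.0456, missed that limit, so that by this rule the test cannot tell. In the other 9 groups the lower bound was above 0.1, a count chosen after the values were seen. Among genes of like GC in those 9 groups a trend with length was therefore left.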

How the results depend on the processing

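Tests in this part chosen only after the result was seen were centring on length and GC, adjustment within each table for lists and named genes, the unadjusted p for splicing, the signed combination, and the directions of retention and of cassette exons. No paired analysis was possible because the tables hold 1 value per group and none per sample. A replicate block, leaving out each replicate and another count tool were therefore not run, and the unknown depth limits what the shares of spliced reads can show. Of the alternatives for results that answer a comparison, 54 gave the same answer, 31 moved a count and 5 made a call appear. A count of like size was taken as the same answer even where its members differed, and so was a count of 0 in both settings. For the mutant with ABA, the count after centring was taken as the same although 54.4% of the calls were kept. For named genes a pseudocount was tried, and centring where a length and GC value was known. Of these alternatives 419 kept the direction and the call and 23, all with centring, lost the call. With the adjustment within each table, named genes past the threshold went from 82 to 82 for ABA in wild type, from 66 to 50 for the untreated mutant and from 83 to 75 for the mutant with ABA. Single lists and directions gave the same answer, called or not called, in 98 alternatives, lost a call in 12, gained one in 9 and reversed in 5. For ABA in wild type, 4597 loci passed with an absolute log2 fold change of at least 1, 3461 of at least 1 with a pseudocount of 1, 4440 with 0.1, and 4559 with median centring and that minimum. For the untreated mutant the corresponding counts were 272, 99, 234 and 272, with 1323 at q under 0.01, 1126 with the adjustment within the table and 1112 with that adjustment over loci of at least 1 FPKM, and for the mutant with ABA they were 595, 256, 530 and 594, with 3928 at q under 0.01. The minimum fold change and the lower q are stricter by construction. For splicing in wild type, 0 events passed with a change of at least 10 percentage points, 0 adjusted again over genes of at least 1 FPKM, 0 without events of p 0 and 507 with an unadjusted p under 0.05. For the untreated mutant these counts were 0, 0, 0 and 604. For the mutant with ABA, 1 event passed at an adjusted p under 0.01, 1 with at least 10 points, 1 without events of p 0, and 715 with an unadjusted p. The share of introns with more retention turned below 50% for ABA in wild type, to 48.0% over all introns with a change and 48.0% over those under 100% in both groups, and for the untreated mutant to 48.2% and 47.1%. The share of cassette exons with lower inclusion for ABA in wild type turned to 49.3% among exons under 100% in both groups. The cause of these reversals was not tested. Lists standing apart were 1 instead of 3 for the untreated mutant at 2-fold, and for the mutant with ABA 4 instead of 2 at 2-fold and 4 with centring, and the cause was not tested. Genes with both calls went from 0 to 246, 75 and 216 with an unadjusted p for splicing, and events called in both mutant comparisons from 0 to 198 with an unadjusted p, while 171 events passed by the signed combination, which does not ask for a call in each.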

Other observations

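Gene families beyond the fixed lists were tested in the same way, and all tests of families in this part were chosen after the values were seen. In wild type with ABA, 89 of 148 ribosomal proteins of the large subunit fell (adjusted exact p = 2.57e-11), and 63 did after centring on length and GC (adjusted exact p = 0.00491). Of 52 WRKY transcription factor genes 31 rose (adjusted exact p = 6.31e-05), and of 50 NAC genes 29 rose (adjusted exact p = 0.000215). All 9 proline-rich extensin-like genes, of the cell wall, fell (adjusted exact p = 0.00150), as did 12 of 16 genes with the symbol EXPA (adjusted exact p = 0.010).

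In untreated rbm25-1, cysteine-rich receptor-like kinase (CRK) genes were the family with the smallest p, with 12 of 20 higher than in wild type (adjusted exact p = 1.83e-07), 10 after centring and 8 with the adjustment within the table. Of 27 receptor-like protein genes 10 were higher (adjusted exact p = 0.000419), and of 9 proline-rich extensin-like genes 6 were higher (adjusted exact p = 0.000592, and 0.628 with the adjustment within the table). With ABA, 16 of 38 receptor-like protein genes (adjusted exact p = 0.0170) and all 8 tested proline-rich extensin-like genes (adjusted exact p = 0.000246) were higher in the mutant. Of 24 heat shock protein genes 16 were higher under ABA (adjusted exact p = 6.73e-05), and of 25 histone genes 13 were lower (adjusted exact p = 0.00104). Both calls were lost after centring, with adjusted exact p of 0.108 and 0.977. Across the 3 comparisons 58, 16 and 28 tests of families passed in the order wild type, untreated mutant and mutant with ABA, out of 1056, 1038 and 1032, and 43, 9 and 6 of them also passed after centring.

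Short transcripts of microRNA genes were lower in the mutant, 8 of 21 untreated and 11 of 22 with ABA, with 0 higher in either. As a family they passed as deposited (adjusted exact p = 0.00486 and 0.00475) and not after centring (adjusted exact p = 0.104 and 0.092). Their median log2 went from -0.71 to -0.59 untreated and from -1.15 to -1.0 with ABA. With centring 6 were lower and 1 higher untreated, and 8 lower and 0 higher with ABA. In wild type, ABA lowered 8 of 23 microRNA genes and raised 1. The fall in the mutant was not particular to microRNA genes. Among genes annotated as ncRNA, 22 of 97 were lower and 3 higher untreated, and 43 of 96 lower and 2 higher with ABA. With centring 21 of these ncRNA genes were lower and 4 higher untreated, and 18 lower and 4 higher with ABA. Their median log2 with ABA went from -0.48 to -0.24. Of all tested loci, 1314 of 19327 untreated and 2301 of 19244 with ABA were lower after centring. Splicing events in the ABA and splicing-factor lists did not stand apart from other events at an unadjusted p under 0.05, with a smallest adjusted exact p of 0.184. SR factors had 8 of 51 events at that p in the untreated mutant and 8 of 46 with ABA.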
